A study of Mus musculus with 2 samples.

How the data were processed

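PolyA plus RNA-seq was deposited for the embryonic facial prominence, the tissue that builds the face, of B6NCrl mouse embryos at 12.5 days. Per the labels, 2 biological replicates were made, replicate 1 from a pool of 120 embryos and replicate 2 from a pool of 88, both of mixed sex. Per the labels, each library started from 10 ng of RNA, was primed with oligo-dT, received ERCC spike-in RNAs and was fragmented by Nextera tagmentation. The labels give 1 tissue and 1 age, so both samples formed 1 group and no comparison between conditions could be made.

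Each library came with gene and transcript tables on the mouse assembly mm10, made with GENCODE annotation release M21 and again with release M4, per the deposited descriptions of the files. The aligner and the quantifier are not given in the sources used here. Per the file headers, each gene table holds an expected count (an estimated number of reads per gene that need not be whole), TPM (a length-corrected share of all transcripts) as a maximum-likelihood and as a posterior mean estimate, and FPKM. The deposited TPM was used for levels, the deposited expected count for depth, counting intervals and alternative scalings, and the deposited FPKM for 1 alternative. Per the file headers, the transcript tables also give the percent of a gene's abundance carried by each transcript. The deposited credibility bounds of the TPM were not used, because their level is not stated. The effective length of long features was the annotated length minus 99 bases. Between 9.08% and 10.6% of rows held a fractional expected count, so reads matching several features had been divided between them. Values of near-identical copies, among them Hba-a1 and Hba-a2, are therefore uncertain. The strand setting is not given in the sources used here, so overlapping antisense genes such as Xist and Tsix cannot be separated.

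The M21 gene tables held 81881 rows, of which 55536 were genes. All of these gene IDs matched the GENCODE M21 annotation used here for names, biotypes and mm10 coordinates. Of the 43346 genes of the M4 tables, 42462 matched by ID without version and 884 did not. The remaining rows were 26248 features named by number, with a median length of 73 bases, 96 ERCC spike-ins and 1 phiX row. Summed expected counts in the M21 tables were 28705073 for replicate 1 and 41092194 for replicate 2. Spike-ins took 2.85% and 3.10% of these counts, rows named by number 0.000139% and 0.000114%, and the phiX row 0. Rows that name no gene stayed out of library sizes for count scaling.

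Genes with a TPM of at least 1 in both replicates were counted as detected. Levels are given as mean ± SD over n = 2. An exact 2-sided sign-flip test on 2 libraries cannot go below p = 0.5, so levels within the tissue were described without p-values. Replicate 2 was set against replicate 1 by log2((TPM + 1) of replicate 2 over that of replicate 1), which understates differences of low genes. This sets 1 library against 1 library, so no p-value across genes was computed, and the differences have no replicate check. For each gene list, the median log2 ratio was placed among 10000 random lists of the same size, matched on expression in 20 bins of mean log2(TPM + 1). Lists outside percentiles 2.5 to 97.5 are called outside the random range, which describes these libraries and not a condition. Named genes carry an exact conditional (Clopper-Pearson) 95% interval of the ratio of rounded expected counts, scaled by the summed counts of genes. The SD of the spike-in log2 ratios carries a percentile bootstrap interval over spike-ins. Count ratio intervals, and the limit of 3 counts used for a count of 0, cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

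The tests between replicates and releases, the alternatives other than the pair added later, the 38 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per list, the 4 members with the highest mean TPM, up to 4 members under a TPM of 1 in both replicates, and every member of lists of up to 8 genes. It also took the 20 highest nuclear protein-coding genes other than ribosomal proteins. From the replicate comparison it took the 10 genes per direction with the largest log2 ratio, at a mean TPM of at least 5 and a summed count of at least 100. From the annotation releases it took the 10 with the largest difference going the same way in both replicates. All genes of the isoform list could also be named. A few genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

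The procedure was tested on simulated data, drawn for 18020 real genes from their mean counts and library sizes, after the deposited values had been explored rather than before. For the comparison of the replicates, all 50 genes changed 3-fold and all 50 changed 4-fold passed the log2 threshold of 1, as did 18 of 50 changed 2-fold and 0 of 50 changed 1.5-fold. Of 17820 unchanged genes, 4 passed it. The count interval covered the true ratio in 95.6% of 2000 genes under counting error. Of 200 lists of 12 genes shifted by 0.3, 200 fell outside the random range, against 9 of 200 unshifted lists. Members of these lists were drawn at random, so they did not vary together, and no smaller shift was tried. The gene-wise spread added to the simulation was set smaller than that between the real libraries. The real SD of the log2 ratio was 0.16 at a mean TPM of at least 5, so the simulated rates describe a quieter setting.

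Alternatives were other TPM minimums and pseudocounts, filters on low genes, posterior mean TPM, FPKM, TPM rescaled to nuclear protein-coding genes, the older annotation release and leaving out each replicate. Expected counts were also scaled with edgeR's TMM (edgeR 4.0.16) and DESeq2's median-of-ratios (DESeq2 1.42.0) in R 4.3.3, over 18739 genes with at least 10 rounded counts in both libraries, and TPM was scaled on the spike-ins. Centring on GC content and leaving out the Ccl21 copies were added after the data were seen. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.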

Results

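Gene expression was measured in the facial prominences of mouse embryos at 12.5 days by polyA plus RNA-seq, in 2 libraries from separate pools of 120 and 88 embryos. Expected counts summed to 28705073 in replicate 1 and 41092194 in replicate 2. The labels state no question beyond the tissue and its age. The data therefore answer which genes this tissue expressed, how far both pools differed, and which values depended on the annotation used to make them. Levels are deposited TPM values, given as mean ± SD with n = 2 throughout, and positions are on mm10.

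The facial tissue expressed 13382 of 22028 protein-coding genes at a TPM of at least 1 in both replicates, and 1600 of them at 100 or more. Actb, the cytoplasmic beta-actin, was the highest nuclear protein-coding gene outside the ribosomal proteins, at 11240 ± 388 TPM. It was followed by the embryonic beta-like globin Hbb-y at 7369 ± 474, the alpha globin Hba-a2 at 5594 ± 363, the ferritin light chain Ftl1 at 4154 ± 113 and the cyclophilin Ppia at 3991 ± 16.6. The histone Hist1h2ap (3806 ± 49.4 TPM), the elongation factor Eef1a1 (3206 ± 99.6 TPM) and the thymosin Tmsb10 (3156 ± 33.9 TPM) came next. Several of these genes have near-identical copies or pseudogenes, so their values depend on how shared reads were divided. Replicate 1 alone passed the minimum for 195 further genes and replicate 2 alone for 220.

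Transcription factors that pattern the facial mesenchyme were expressed throughout the regional lists. Msx1, a homeobox gene of facial mesenchyme and tooth development, reached 313.5 ± 7.24 TPM. The general mesenchyme list was detected in 18 of 18 members with a median of 32.9 TPM, led by Prrx1 (143 ± 4.00 TPM), Prrx2 (88.7 ± 8.05 TPM), Twist1 (64.4 ± 3.25 TPM) and Snai2 (60.4 ± 6.70 TPM). Alx1, a homeobox gene of the frontonasal region (chromosome 10, 102998707 to 103030215), stood at 126 ± 33.4 TPM, with Pax3 at 25.8 ± 4.95 and Alx4 at 20.4 ± 1.92. Barx1, a marker of proximal first-arch mesenchyme (chromosome 13, 48662998 to 48666507), stood at 126 ± 59.5 TPM, beside Pitx1 at 100.2 ± 32.2 and Lhx8 at 52.3 ± 6.70. Among the Dlx genes, which set positions along the arch, Dlx5 was at 67.8 ± 18.4 TPM and Dlx1 at 59.7 ± 12.1, while Dlx4 was at 4.15 ± 0.41. The palate list was detected in 8 of 8 members, led by Osr2 at 91.0 ± 1.65 TPM and Osr1 at 68.7 ± 0.601, with Tbx22 lowest at 9.11 ± 2.52.

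**Figure D1:**
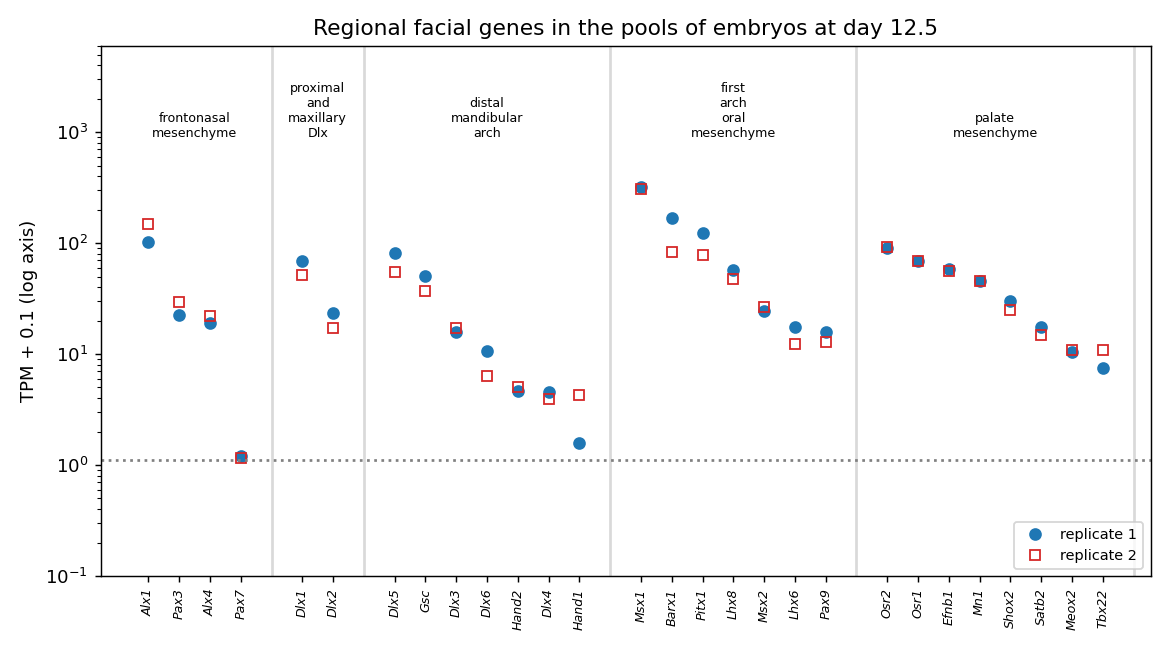
TPM plus 0.1 on a log axis of regional genes in replicate 1 (filled circles) and replicate 2 (open squares), grouped by list, with a dotted line at a TPM of 1. Alx1 lies higher in replicate 2, Barx1, Pitx1 and Dlx5 lie higher in replicate 1, and Msx1 overlaps at 319 and 308 TPM.

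Hox genes, which pattern the body behind the first arch, were detected in 5 of 39 members, and their median was 0.08 TPM. Hoxa2 (chromosome 6, 52162417 to 52164831) was highest at 13.0 ± 1.65 TPM, followed by Hoxd1 at 9.29 ± 0.0495, Hoxb2 at 4.06 ± 1.44 and Hoxd8 at 1.63 ± 0.58. Hoxa13 had 1 count in replicate 1 and 0 counts in replicate 2, a level at which presence was not detectable at this depth.

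Epithelial genes were detected in 18 of 18 members with a median of 30.5 TPM. The keratins Krt14 (89.9 ± 5.84 TPM), Krt15 (65.2 ± 10.7 TPM) and Krt5 (60.3 ± 3.90 TPM) and the adhesion molecule Epcam (69.7 ± 0.742 TPM) were highest. Genes of tooth initiation were detected in 12 of 13 members but had a median of only 2.59 TPM. Lef1 at 83.8 ± 0.134 TPM and Sostdc1 at 48.3 ± 1.97 stood far above it. Genes linked to orofacial clefts were detected in 20 of 20 members, with Fgfr1 at 123 ± 1.58 TPM and Fgfr2 at 95.6 ± 0.891.

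Signalling genes were present for each pathway examined. The hedgehog co-receptor Gas1 stood at 222 ± 24.6 TPM and the signal transducer Smo at 54.7 ± 0.608, and all 11 members of that list were detected. BMP targets of the Id family were high, with Id3 at 484 ± 4.99 TPM and Id2 at 355 ± 4.09, and 16 of 17 members of the BMP list were detected. The WNT list was detected in 16 of 16 members, with Ctnnb1 at 618 ± 11.6 TPM and the secreted antagonist Sfrp2 at 411 ± 0.537. The retinoic acid binding proteins Crabp1 (451 ± 35.8 TPM) and Crabp2 (371 ± 6.84 TPM) led a list detected in 14 of 15 members, with Cyp26c1 at 0.825 ± 0.0495. The FGF list was detected in 14 of 14 members, with Dusp6 at 71.0 ± 0.212 TPM. In the endothelin list (8 of 8 detected) the receptor Ednra stood at 39.1 ± 2.00 TPM and the ligand Edn1 at 1.52 ± 0.368. In the PDGF list (6 of 6 detected) Pdgfra stood at 98.7 ± 1.12 TPM and Pdgfrb at 50.8 ± 1.13.

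Cartilage genes exceeded late bone genes in both replicates. The cartilage collagen Col2a1 stood at 317 ± 32.3 TPM, its regulator Sox9 at 112 ± 5.78, Col9a3 at 111 ± 19.6 and Col9a1 at 104 ± 1.36, and the cartilage list was detected in 14 of 15 members with a median of 41.3 TPM. The bone list had a median of 1.94 TPM and was detected in 5 of 10 members. Runx2, the early regulator of osteoblasts, stood at 24.8 ± 0.233 TPM and Sp7 at 7.04 ± 0.467, while Ibsp was at 0.43 ± 0.099, Dmp1 at 0.30 ± 0.0566 and Bglap at 0.16 ± 0.226. Mepe had 0 counts in both libraries, which allows up to 3 counts in each. Matrix genes of the connective tissue were all detected (14 of 14), with Col3a1 at 933 ± 1.53 TPM, Col1a2 at 499 ± 36.4 and Col1a1 at 445 ± 60.1.

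Markers of other cell types were present at widely differing levels. Erythroid genes were highest, with a median of 531 TPM, and the 7 listed globins together made up 1.95% of all TPM in replicate 1 and 1.78% in replicate 2. Neuronal genes were detected in 15 of 15 members with a median of 39.3 TPM, led by Tubb3 at 136 ± 30.2 and Nefl at 100.5 ± 19.1. Muscle genes were detected in 14 of 15 members, with Actc1 at 187 ± 23.0 TPM and the muscle regulator Myog at 54.5 ± 7.17. Endothelial genes had a median of 18.4 TPM (10 of 10 detected, Emcn at 27.6 ± 0.0778) and macrophage genes 6.49 TPM (10 of 11 detected, C1qb at 22.7 ± 0.764). Glial genes of crest origin had a median of 7.92 TPM (7 of 8 detected), with Fabp7 at 136 TPM on average and Sox10 at 16.7 ± 0.389. The eye list had a median of 7.97 TPM (6 of 8 detected), and its lens crystallin Cryaa (chromosome 17, 31677807 to 31681733) reached 155 ± 94.3. Melanoblast genes had a median of 2.38 TPM (6 of 7 detected), at 1.41 in replicate 1 and 3.36 in replicate 2, and pituitary genes 1.42 TPM (3 of 7), at 1.54 and 0.69. Forebrain genes had a median of 2.00 TPM (6 of 10) and liver genes 1.94 TPM (4 of 7).

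Cells of the tissue carried high levels of cycling and growth genes. The proliferation list had a median of 189 TPM (13 of 13 detected), with the cyclin Ccnd2 at 687 ± 32.1 and Cdk1 at 297 ± 7.45. In the older annotation release Ccnd2 was lower, at 168 TPM in replicate 1 and 173 TPM in replicate 2. The imprinted growth list had a median of 325 TPM (12 of 12 detected), with the growth inhibitor Cdkn1c at 1309 ± 8.65 and the growth factor Igf2 at 557 ± 13.8. Glycolysis and hypoxia genes had a median of 173 TPM (10 of 10 detected), with Eno1 at 1213 ± 28.2. Immediate early and stress genes had a median of 3.56 TPM (9 of 11 detected), with Fosb at 0.035 ± 0.00707. Across all lists except the isoform list, 345 of 407 genes were detected.

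The pools were then set against each other. Lens genes were higher in replicate 2: Cryaa was at 88.1 TPM in replicate 1 and 221 TPM in replicate 2 (count ratio interval 2.35 to 2.61), Cryba1 at 52.6 and 124 TPM (2.15 to 2.57) and Crybb1 at 36.3 and 74.6 TPM (1.85 to 2.26). The crystallins Crybb3, Crygn and Crygc, the melanocyte channel Trpm1 and the retinaldehyde dehydrogenase Aldh1a1 (7.61 and 23.9 TPM, interval 2.73 to 3.57) were also among the 10 genes furthest above. Barx1 was higher in replicate 1, at 168 against 83.9 TPM (interval of replicate 2 over replicate 1, 0.473 to 0.520), as was the inner ear gene Oc90 at 40.9 against 17.9 TPM (0.376 to 0.458). Further genes higher in replicate 1 were the WNT mediator Dvl1, the cartilage collagen Col11a2 and the heparan sulfate enzyme Hs6st1. Greb1l, Gm45799 and Mamdc4 were lower in replicate 2 by more in TPM than in counts. Their count ratio intervals were 0.755 to 0.973, 0.487 to 0.774 and 0.491 to 0.801, beside log2 TPM ratios of -0.91, -1.75 and -1.05.

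Both ends of the ranking were taken by members of the Ccl21 gene family. Gm13304 had 0 counts in replicate 1 and 401 in replicate 2, at least 93.5-fold higher when 3 counts are allowed for the 0, with an exact count ratio interval from 75.8 upward. In the other direction, Ccl21b had 162 counts in replicate 1 and 0 in replicate 2, at least 77.1-fold lower by the same limit (exact interval of replicate 1 over replicate 2 from 62.0 upward). The expected counts above 0 of both genes, and those of the annotated Rps12 copy Rps12-ps3 (19.2 and 4.34 TPM), were not whole numbers, so these values are uncertain.

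Across all 22028 protein-coding genes the log2(TPM + 1) values had a Pearson r of 0.998 and a Spearman rho of 0.991, which are correlations across genes and not across independent replicates. A log2 ratio of at least 1 was reached by 21 genes in replicate 2 and by 19 in replicate 1. Many of these genes, in both directions, had expected counts that were not whole numbers. Examples are Duxbl2 (107.15 and 0 counts) and Gm14288 (0 and 216.16 counts), chosen after their values were seen. Both numbers therefore depend in part on how shared reads were divided. At a mean TPM of at least 5 the numbers were 10 and 6 of 10920 genes, and 98.8% of these genes lay within 0.5. Over 15249 genes together, rounded counts gave a chi-square of 91447 on 15248 degrees of freedom. It sets separate pools against counting error alone and says nothing of single genes. Amplified reads and reads divided between copies can also exceed counting error, so no conclusion about the pools is drawn from it. With a pseudocount of 0.1 the number was 745 in place of 40 genes, and scaling on the spike-ins turned the split of 21 and 19 into 16 and 34.

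**Figure D2:**
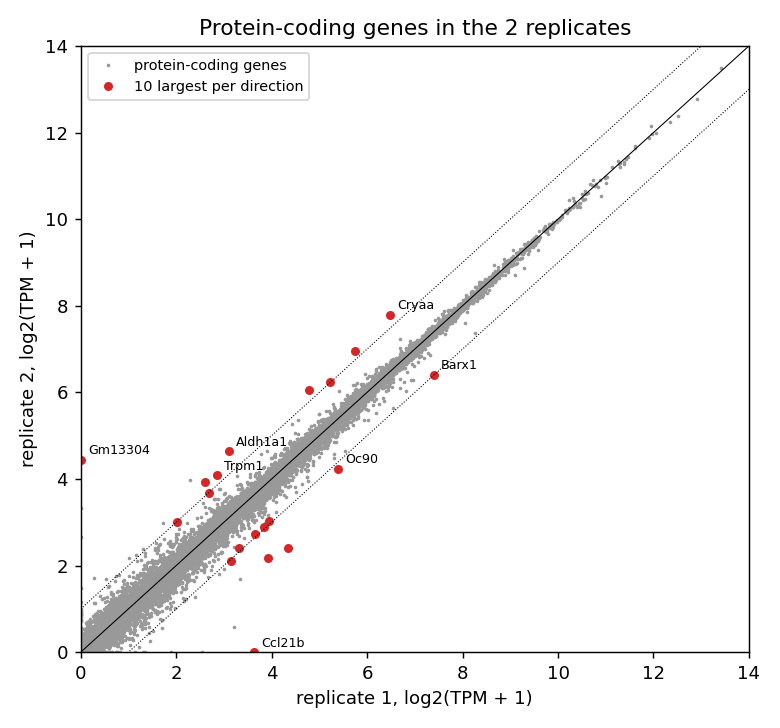
Each grey point is a protein-coding gene, with log2(TPM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis; red points are the 10 genes per direction with the largest ratio, the solid line marks equality and the dotted lines a log2 difference of 1. Gm13304 lies on the y axis and Ccl21b on the x axis, and Cryaa lies above and Barx1 below the diagonal.

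Of 37 gene lists, 6 lay above and 8 below the range of random lists, where 1.85 would lie outside if the genes of a list varied independently. Genes of 1 tissue or cell type can vary together, so the excess over 1.85 does not measure how far chance is exceeded. Melanoblast genes lay above, with a median log2 ratio of 0.73 (percentile 100, higher in 7 of 7 members), and Pmel stood at 20.7 and 37.5 TPM. Frontonasal genes lay above at 0.38 (percentile 99.99, 4 of 5 members), with Alx1 at 103 and 149.9 TPM. The eye list lay above at 0.36 (percentile 100, 7 of 8 members), and the retinal regulators Rax (9.18 and 11.0 TPM) and Six6 (4.59 and 6.52 TPM) went the same way as the crystallins. Skeletal muscle genes lay above at 0.25 (percentile 100, 13 of 15 members), with Tnnc1 at 52.7 and 70.9 TPM. Proliferation genes lay just above at 0.05 (percentile 97.55, 10 of 13 members), and inside the range after GC centring (0.03, percentile 94.3).

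Regional genes of the first arch lay below. Dlx1 and Dlx2 had a median log2 ratio of -0.42 (percentile 0.10, 2 of 2 members lower), and Dlx1 stood at 68.3 and 51.1 TPM. The oral mesenchyme list had a median of -0.28 (percentile 0, 6 of 7 members lower), with Pitx1 at 123 and 77.4 TPM and Lhx6 at 17.5 and 12.1 TPM, while Msx2 stood at 24.2 and 26.7 TPM. The distal mandibular list had a median of -0.16 (percentile 1.47, 4 of 7 members lower), with Dlx5 at 80.8 and 54.8 TPM, whereas Hand1 (chromosome 11, 57828705 to 57832818) stood at 1.47 and 4.20 TPM (count ratio interval 2.04 to 3.95). After GC centring the distal mandibular list lay inside the range (-0.13, percentile 3.35). Neuronal genes had a median of -0.31 (percentile 0, 15 of 15 members lower), with Tubb3 at 158 and 115 TPM. Forebrain genes had a median of -0.28 (percentile 0.07, 8 of 10 lower), although Pax6 stood at 10.7 and 16.2 TPM. Cartilage genes (-0.16, percentile 0, 12 of 15 lower), erythroid genes (-0.13, percentile 0.01, 10 of 12 lower) and epithelial genes (-0.10, percentile 0.19, 12 of 18 lower) also lay below. Within the epithelial list Krt15 went the other way, at 57.6 and 72.8 TPM.

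The remaining lists lay inside the range. They included the palate list at -0.01 (percentile 41.2), with Tbx22 at 7.33 and 10.9 TPM, and the general mesenchyme list at 0.04 (percentile 88.9). Tooth, cleft, hedgehog, BMP, FGF, WNT, endothelin, retinoic acid, PDGF, bone, matrix, glial, pituitary, endothelial, macrophage, liver, stress, glycolysis, imprinted and X-inactivation lists also lay inside. Of these, the matrix list (0.05, percentile 95.8) lay outside with TMM scaling (98.9), in the older release (97.9) and after GC centring (99.5), and the imprinted list (-0.05, percentile 5.91) with TMM scaling (0.84). The Hox list also lay inside, but with 34 of 39 members undetected its median is held near 0 by the pseudocount, and the summed TPM of the Hox genes was 31.7 in replicate 1 and 39.8 in replicate 2 (count ratio interval 1.14 to 1.33). Scaling on the spike-ins, whose summed TPM was higher in replicate 2 by 0.14 on the log2 scale, lowered the list medians, by less for lists of low genes because of the pseudocount. The proliferation median, smaller than this shift, turned from 0.05 to -0.09, and places among random lists were not recomputed.

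**Figure D3:**
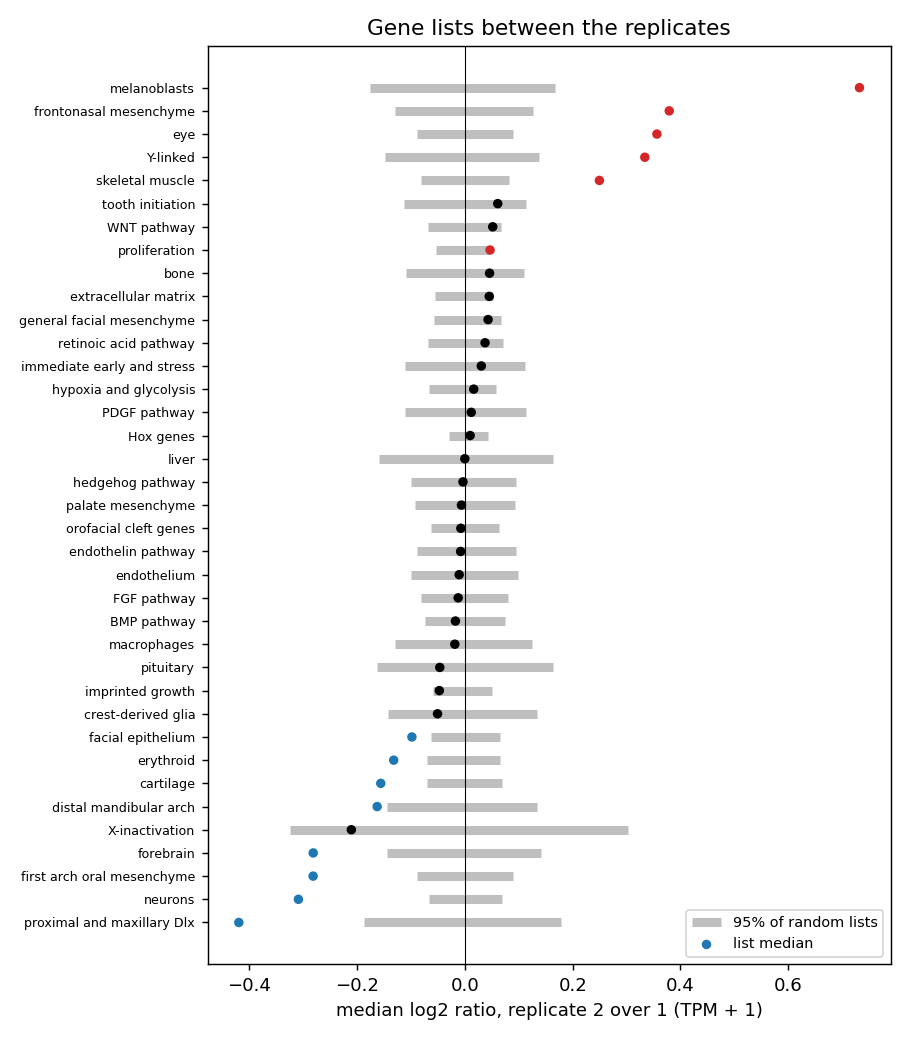
Median log2 ratio of replicate 2 over replicate 1 for each gene list (points; red above, blue below and black within the random range), with grey bars for the central 95% of 10000 random lists matched on expression. Melanoblast genes lie furthest to the right at 0.73 and Dlx1 with Dlx2 furthest to the left at -0.42.

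Transcripts of the sex chromosomes went in opposite directions. The Y-linked genes were all higher in replicate 2, Ddx3y at 18.4 and 25.5 TPM (count ratio interval 1.36 to 1.55), Kdm5d at 9.19 and 13.6 TPM (1.20 to 1.47), Uty at 14.1 and 16.5 TPM (1.14 to 1.36) and Eif2s3y at 34.0 and 37.0 TPM (1.06 to 1.26). Their median log2 ratio was 0.33 (percentile 100). Xist, the RNA that coats the inactive X chromosome, was lower in replicate 2, at 25.8 and 20.4 TPM (0.761 to 0.807), while the list of Xist and Tsix lay inside the random range (percentile 8.31) but outside it in the older release (percentile 2.05). Tsix, which overlaps Xist on the other strand, stood at 4.96 and 4.58 TPM, and reads of this pair cannot be separated without a strand setting. Per the labels both pools held males and females, and these transcripts were present in both.

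ERCC spike-ins, RNAs added to each sample per the labels, were set beside facial genes of the same count. Of 96 spike-ins, 78 had counts in both libraries, and 63 of these had a mean count of at least 10. Their log2 ratio had an SD of 0.27 (bootstrap 95% interval 0.20 to 0.32) and a median of 0.14. Protein-coding genes matched on count had an SD of 0.45, 1.69 times as large, and the SDs estimated from the interquartile range were 0.17 for spike-ins and 0.19 for genes. Counting error alone would give the 63 spike-ins an SD of about 0.25. For the 21 spike-ins with at least 1000 counts in replicate 1, the SD was 0.069 where counting error alone would give 0.027. The spike-in SD was 0.50 with a mean count of at least 1 and 0.15 with at least 100. Since spike-ins do not pass through dissection and pooling, a larger SD of genes is no test of a difference between the pools.

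**Figure D4:**
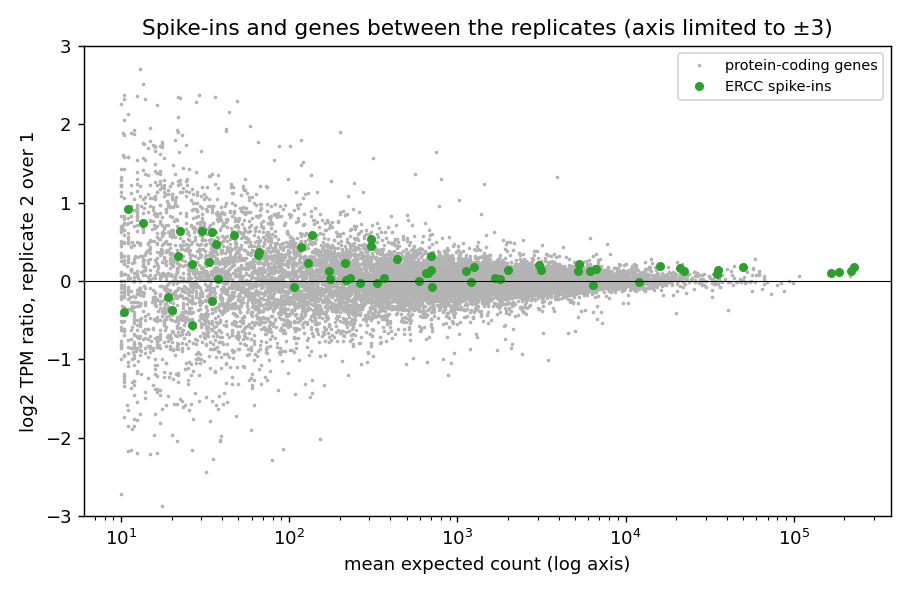
Log2 TPM ratio of replicate 2 over replicate 1 against the mean expected count on a log axis, for protein-coding genes (grey) and the 63 ERCC spike-ins with a mean count of at least 10 (green), with the y axis limited to 3 on either side of 0. Spike-ins lie around a median of 0.14 and spread less as counts rise.

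Transcript tables gave the share of each gene carried by its leading isoform. Pkm-201 of the glycolytic gene Pkm carried 92.7 ± 0.53%, Msx1-201 carried 93.7 ± 0.481% and Col2a1-201 carried 66.9 ± 0.997%. For Trp63, a regulator of epithelium, transcripts starting at the internal position (chromosome 16, 25801916) carried 84.4 ± 4.84% and those starting upstream (25683763) carried 15.6 ± 4.84%. These positions were chosen after the values were seen. The upstream share was carried by Trp63-206 alone, an annotated transcript of 4 exons. The longer upstream transcripts Trp63-202, Trp63-207 and Trp63-208, of 13, 11 and 14 exons, stood at 0 TPM in both replicates. Of 22 genes with several annotated transcripts, 17 had the same leading isoform in both replicates, and Cd44, Fgfr2, Fgfr3, Igf2 and Trp63 did not. The median leading share was 38.6%, and Vegfa-202 differed most between the replicates, at 38.2% and 56.0% in the newer release, against 23.1% and 27.3% in the older. Other shares depended more on the release. Sox5-202 carried 31.3% and 35.9% in the newer release but 2.01% and 3.95% in the older. For Sox6, the newer release was led by Sox6-211, which had no value in the older. Sox6-203 carried 53.1% and 53.9% in the older release and 0% in the newer. Such shares are model estimates from short reads, and no interval was computed for them.

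The same libraries gave other values for some genes when another annotation release was used. Among 21474 protein-coding genes present in both releases, 283 differed by at least 1 on the log2 scale in the same direction in both replicates, 211 higher and 72 lower in the newer release. Usp50 stood at 2.54 ± 0.0778 TPM in the newer and 199 ± 2.18 TPM in the older release, and Nupl1 was listed at 0 in the newer release and at 41.4 ± 1.34 TPM in the older. The phosphatase gene Ptp4a1 (ENSMUSG00000026064.16, chromosome 1, 30940302 to 30949309) stood at 3.45 ± 0.297 TPM in the newer and 235 ± 20.1 TPM in the older release. The newer release lists a second gene of the same name over the same region (ENSMUSG00000117310.1, 30940302 to 30949770), at 219 ± 19.9 TPM, so the summed level of both IDs differed far less than that of the first. Ulk4 went the other way, from 3.56 ± 0.106 TPM in the older to 152 ± 3.76 TPM in the newer release, as did Platr25 (1.00 and 33.3 ± 0.467 TPM) and Hist1h2br (0.89 ± 0.212 and 30.4 ± 5.44 TPM). Of the listed genes, Ccnd2, Mef2c, Sox6 and Ndn changed by this much, Ccnd2 from 168 to 665 TPM and Ndn from 266 to 109 TPM in replicate 1. Mef2c, Sox6 and Ndn were named because they were the listed genes that differed. The correlation across genes between releases was 0.994 in replicate 1 and 0.995 in replicate 2.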

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

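Signals outside the protein-coding comparisons were compared with the limit that a count of 0 allows, 3 counts, as a check fixed by rule. Sums over many rows readily exceed so low a limit, so passing it says little about these signals. Features named by number held 40.0 counts in replicate 1 and 47.0 in replicate 2, over 9 and 6 of their 26248 rows. Genes annotated as ribosomal RNA held 264787 counts (0.922%) in replicate 1 and 386622 counts (0.941%) in replicate 2 in the newer release, of which CT010467.1 alone took 264763 and 386600. In the older release their shares were 8.74e-05% and 5.63e-05%, so this signal depended on the annotation. Processed pseudogenes held 182525 counts (0.636%) and 254723 counts (0.620%). Genes of the older release without a match in the newer one held 88452 counts in replicate 1 and 119773 counts in replicate 2 in the older tables. No explanation was tested for these signals.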

How the results depend on the processing

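GC centring and leaving out the Ccl21 copies were chosen after the data were seen; the other alternatives were planned. The count of genes with a log2 ratio of at least 1 between the replicates was 40. It was 745 with a pseudocount of 0.1 (395 higher in replicate 2, 350 in replicate 1) and 16 at a mean TPM of at least 5 (10 and 6, fewer genes being tested), and spike-in scaling left 34 higher in replicate 1. Expected counts in place of TPM, scaled with TMM or median-of-ratios, gave 25 and 15, and 23 of the 40 genes were kept under either, unit and scaling having changed together. The spike-in SD moved from 0.27 to 0.50 at a mean count of at least 1 and to 0.15 at 100 or more, which keep more or fewer spike-ins of low count. The isoforms leading in the newer release had a median share of 38.6% there, over all 22 genes. In the older release their median share was 35.2%, over the 21 of 22 present in both and whether or not they led there. These medians cover unlike sets, and the cause was not tested. Detected genes stayed between 10776 and 14216, and detected list genes between 290 and 359. All 14 lists outside the random range stayed outside with a pseudocount of 0.1, with TMM and in the older release. TMM added the matrix and imprinted lists, the older release the matrix and X-inactivation lists, each to 16, and GC centring the matrix list. With GC centring 12 of the 14 stayed outside: the distal mandibular median became -0.13 (percentile 3.35) and the proliferation median 0.03 (94.3). Spike-in scaling shifts genes together and tests no list's place among random lists; the proliferation median became -0.09. List levels moved by more than 1 SD in 15 of 37 lists in the older release, and in 34 of 37 both with FPKM and with TPM rescaled to nuclear protein-coding genes, which change the unit of all genes. Leaving out a replicate was not possible where replicates were set against each other. No paired analysis was possible because there is 1 group. Depth limits genes with few counts, for which a pseudocount decides the ratio.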

Other observations

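Further gene lists were written after the main comparisons had been seen, and the tests on GC content, retinal and pigment epithelium genes, first-arch genes and the Ccl21 copies were chosen after the result was seen, as was the measure of spread for the GC tests. Pigment epithelium genes had a median of 2.46 TPM (8 of 10 detected) and a median log2 ratio of 0.63 between replicate 2 and replicate 1 (percentile 100), with 5 of the 10 also in the fixed lists and Trpm1 also seen before. Inner ear genes had a median of 0.507 TPM (4 of 12 detected), a list written after the low Oc90 value in replicate 2 had been seen and holding that gene, with Gata3 at 18.6 and 17.6 TPM and Lmx1a at 3.42 and 1.37 TPM. Sensory neuron genes, 3 of them also in the fixed lists, were detected in 12 of 13 members with a median of 13.9 TPM and a log2 ratio of -0.18 (percentile 0.06). The filament gene Prph stood at 40.0 and 27.8 TPM.

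Genes annotated as long intergenic non-coding RNA were led by the nuclear RNA Malat1 at 5452 ± 285 TPM (n = 2), followed by Gm26917 at 4366 ± 203, the imprinted RNA Meg3 at 584 ± 82.0, Gm42418 at 498 ± 13.0 and the imprinted RNA H19 at 390.0 ± 22.9. Gm26917 (39843013 to 39846341) and Gm42418 (39846958 to 39848788) lie side by side on chromosome 17. The origin of their reads was not tested, so their rank rests on the annotation alone. Malat1, Gm26917 and Gm42418 were named as the highest by mean TPM.

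The 4 lens genes of the eye list had a median log2 ratio of 1.12 between the replicates. GC content bias as the whole cause was argued against, since after centring on genes of the same GC content the median was 1.13, above the bound of 0.5 by more than both the half-width of the random-list range (0.12) and the SD across the genes (0.52). A larger share of the whole eye cannot be told apart from more lens alone. The 9 retinal progenitor genes, 6 of them also in the fixed lists, had a median of 0.25 (SD 0.29, percentile 99.96), well below the lens. Of these, Six3 (-0.12) and Hes5 (-0.33) were lower in replicate 2. Pigment epithelium genes had 0.63 (SD 0.34), more than 0.5 times the lens value. Their highest members had been seen before: Trpm1 (1.24), and Pmel, Tyr, Tyrp1 and Dct (0.73 to 0.93), which are also melanoblast genes. Mlana, Slc45a2, Otx2, Oca2 and Rlbp1 had 0.53, 0.38, 0.37, 0.27 and 0.17. A candidate explanation is more lens tissue in the second pool: 6 lens genes with a mean TPM of at least 1, not looked at before this test, had a median of 0.59, past the preset 0.5 by less than their SD of 0.28, and the count ratio interval of Bfsp1 (0.846 to 1.58) included 1. Both explanations concern tissue content. The pools also differed in the number of embryos and in transcripts of the sex chromosomes, and neither was tested as a cause.

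First-arch genes were lower in replicate 2. The oral mesenchyme median was -0.28 before and -0.30 after centring on GC content (percentile 0 of random lists), so centring did not bring it nearer to 0. That argues against GC content bias as the whole cause, the median lying beyond the bound of -0.15 by more than the half-width of the random-list range (0.08). The verdict depends on this measure of spread, which was chosen after the result was seen. By the SD across the 7 genes (0.37), which was used first and describes single genes and not their median, the test was undecided. A lower share of the whole first arch cannot be told apart from changes of single genes, since 9 of 16 first-arch genes lay below the 95% range of single genes at the same level and 1, Hand1, lay above it, too few to decide. No biological explanation other than tissue content was tested.

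The Ccl21 copies differed most between the replicates. Reads shared between near-identical copies may account for this, since 84.2% of the 100-base sequences of 4 copies occurred in another copy. The check is void as a verdict, because 2 of the 6 copies, Ccl21b among them, had no sequence in the transcripts used here. Summed over the copies, counts were 353 and 828, a ratio of 1.64 with an exact 95% interval of 1.45 to 1.87, so the sum also differed by more than counting error.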
